A study of Mus musculus with 21 samples.

How the data were processed

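Methylated DNA was enriched from synovial fibroblasts of Tg197 and WT mice with a methyl-CpG-binding protein kit, per the labels' protocols, after sonication to an average of 250 bp, and libraries were sequenced as paired reads of 100 bp. Fractions eluted at low and high salt were combined, so that sparsely and densely methylated DNA are both represented and cannot be told apart in the values. Per the submitters' processing notes, the tools BWA, TopHat, TopHat2, Cufflinks and Cuffdiff and the build mm9 were used, with no role given. The program that compared the groups, its test and its filters are not given in the sources used here. The gene expression and histone profiles that the labels mention were not analysed here.

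Each of the 4 deposited tables lists regions of at least 500 bp (median 550 bp) that the authors found different between 2 groups, with the nearest gene and a feature class. Per the file headers, the deposited signal of a region is the mean normalized read value of a group, computed by the authors. The 3 values of the single libraries of a group stand packed in 1 cell, as reads divided by 1 size factor per library. Per the file headers, the log2 fold change of a region was computed by the authors, and its values equal the log2 ratio of the group means. Each region carries a p-value and an adjusted p-value of the authors for the region and for its best window, and in the deposited columns no window p is above 0.0001. The regions were therefore already selected for a difference between the groups, and every test below is a retest of selected regions. The number of windows tested was estimated from the ratio of the deposited p and q-values. No region that was not listed has a value, so nothing can be said of it, and shares of gained and lost regions describe the lists and not the genome.

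Columns headed as treatment were read as Tg197 or TNF-treated and those headed as control as WT, and all columns could be assigned to a group (0 columns were left out). The order of values within a cell carries no replicate number, so a library is named by its position in its group, and no pairing of samples could be used. The tables were normalized separately, so tests were made within a table. Whole multiples of the smallest step of a library gave back whole read numbers within 0.1 for 99.86% to 100% of values, which served to describe depth, for limma voom and for the Poisson bound. From 57.0% to 68.4% of read numbers up to 20 were even, as happens when both ends of a pair are counted, so these reads are not independent molecules and intervals cover counting error only. A p was called below the Poisson bound where the authors' p was over 10 times smaller than an exact binomial test of the recovered reads. The depth of a library outside the listed regions is unknown.

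The design fixed before the data were examined named 1 test for each kind of value. Since the values were normalized and given per library, limma with a mean trend was fitted to log2(value + 1) of each listed region, with the Benjamini-Hochberg adjustment over the regions of a table and a threshold of 0.05. Fold changes are on this log2(value + 1) scale, unless named as the authors'. The added 1 shrinks changes of regions with few reads, but a difference of mean logs is set here against the authors' log ratio of means, so a fold can lie above or below theirs. No filter on low values was used. TNF-treated libraries 1 and 2 held identical values and entered as 1 library. The share gained in each feature class and chromosome was compared with the other regions of the table by Fisher's exact test, two-sided, adjusted over classes or chromosomes and tables. A promoter region lies within 3 kb of a transcription start. Overlap between tables was at least 1 bp, with chance from 1000 random rotations along each chromosome, and agreement of direction was tested by Fisher's exact test over 6 pairs of tables. The agreement expected from read level was drawn 10000 times from the share gained in each of 20 classes of read level per table. Classes and chromosomes were also set against regions of the same 20 classes of level, on other autosomes for chromosomes. Gene lists were tested on direction (Fisher's exact test of list genes against other genes of the table, by the mean log2 fold of each gene's regions) and on presence against 10000 random lists matched on gene length. For the covariance of fold changes, unchanged groups were simulated 200 times against the shared WT libraries of the 8-week tables, with no selection of the simulated values. The number of windows that unchanged groups would share was calculated from a bivariate normal distribution.

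Genes named in the text followed a rule fixed before the data were examined. In each table these were the 6 largest promoter gains and losses with an authors' adjusted p under 0.05 and a mean of at least 10 in the higher group, up to 3 genes of each of 21 gene lists with the smallest authors' adjusted p, the 10 genes of the same direction in all 3 Tg197 tables with the smallest worst adjusted p, and Tnf, Tnfrsf1a and Tnfrsf1b. Of 871 list genes 869 were known to the RefSeq gene table and 509 had a region in some table. Of 9615 symbols used by the authors, 9525 (99.1%) matched the RefSeq table of GRCm38.p6, which was used for names and synonyms only. Regions shared between tables were named after their values were seen. Some genes that the rule names are not reported here.

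The alternatives were a stricter authors' threshold (adjusted p under 0.01), a minimum absolute log2 fold of 1, a minimum mean of 10, autosomes only, merging of regions within 1 kb, a pseudocount of 0.1, a 50% overlap, promoter regions only, the region with the smallest p, and leaving out each library in turn. Alternatives chosen after the data were seen were limma voom, adjustment over all windows, removal of regions below the Poisson bound, regions past limma only, matching on read level, lists not matched on length, and removal of chromosome 9. Checks that need a genome sequence, such as CpG density or strain variants, were not made.

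The limma step was tested on simulated data with the regions and means of each table and 1 median spread beyond counting per table. This dispersion was 0 at 3 weeks, 0.023 at 8 weeks, 0.0144 at 11 weeks and 0 for TNF. Far fewer regions were changed than passed in the real data, so the rates describe the simulated setting only. Regions changed 1.5-fold, 2-fold and 4-fold were recovered at 73.1%, 85.1% and 100% at 3 weeks, 13.4%, 59.7% and 90.9% at 8 weeks, 25.4%, 64.2% and 93.9% at 11 weeks and 32.8%, 56.7% and 92.4% for TNF, with 67, 67 and 66 changed regions each. False calls made up 2.3%, 1.8%, 4.7% and 1.6% of calls. With nothing planted in 20 simulations on the 3-week table, a call arose in 1 for overlap, 0 for agreement of direction (Fisher's exact test), 1 for list direction, 2 for list presence and 3 for chromosomes, and planted effects were found in all 20. Statistics used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.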

Results

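DNA methylation was profiled in cultured mouse synovial fibroblasts, the lining cells of the joint that drive tissue damage in arthritis. Cells came from Tg197 mice, which carry a human TNF transgene and develop chronic polyarthritis, and from wild-type (WT) mice. The 21 samples formed 7 groups of 3: Tg197 and WT at 3, 8 and 11 weeks of age, and WT cells at 8 weeks that had been exposed to TNF. Per the labels, cells were used at passages 4 to 5 and the mice were of mixed CBA x C57BL/6J background. In MethylCap-seq, methylated DNA fragments are captured with a methyl-CpG-binding protein and sequenced, so a region's reads follow both its methylation and its CpG content. The data were 4 tables of regions listed as different between 2 groups, 49307 regions in all, with 1 normalized read value per library. Reads recovered within the listed regions ranged from 2230884 to 2875555 per library at 3 weeks, from 695108 to 1143699 at 8 weeks, from 385155 to 544797 at 11 weeks and from 1285304 to 1858694 in the TNF table. The total depth of each library is not known. Of the 3 TNF-treated libraries, 2 held identical values at all 16898 regions and were counted as 1 sample, which left n = 2 against n = 3. Gained means higher in the group the tables head as treatment, read here as Tg197 or TNF-treated cells. The labels do not state whether replicates were separate cultures or animals, so limma p-values measure only the spread between these samples, which may be technical. Fisher's exact tests and the tests at matched read level count listed regions or genes as independent units. Their p-values, and those of rotations and permutations, do not measure the spread between samples. All coordinates are in mm9.

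**Figure D1:**
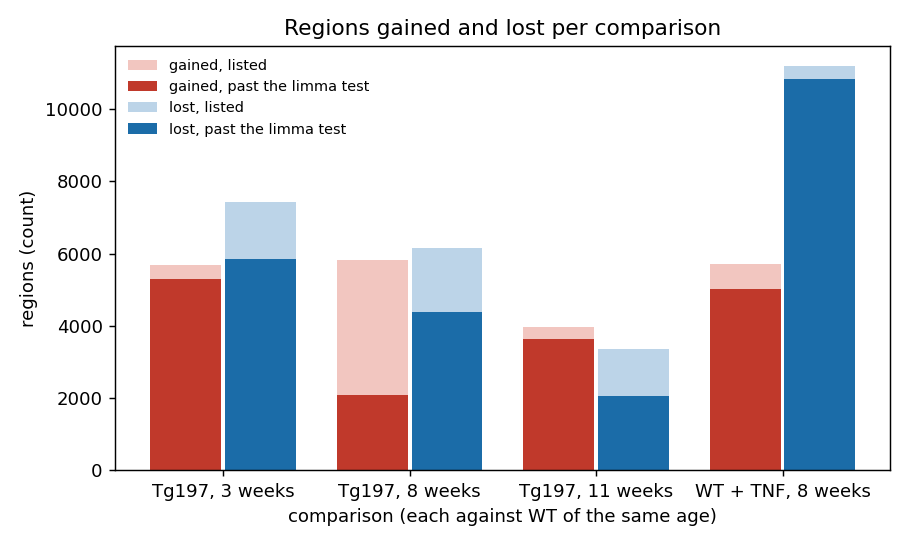
Bars give the number of listed regions with higher (gained) or lower (lost) capture in each of the 4 comparisons, and the number of each that passed the limma test. Gained regions made up 43.4% at 3 weeks, 48.5% at 8 weeks, 54.2% at 11 weeks and 33.8% after TNF.

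The comparison at 3 weeks addressed early disease. Capture rose at the promoter of Mtnr1a, a melatonin receptor gene (chromosome 8, 46154401 to 46155150), from 8.14 ± 5.21 normalized reads in WT to 30.2 ± 8.45 in Tg197 (SD, n = 3 per group), a log2 fold change of 1.97 with a standard error of 0.44 (limma, adjusted p = 0.00213). It rose likewise at the promoters of Diablo, which encodes a mitochondrial activator of caspases (6.07 ± 3.74 to 20.4 ± 3.02, log2 fold 1.77), and of the carbonyl reductase gene Cbr1 (5.78 ± 2.86 to 18.7 ± 2.68, log2 fold 1.61). Capture fell at the promoter of Pdgfd, which encodes a platelet-derived growth factor (chromosome 9, 6170601 to 6171550), from 33.4 ± 4.61 to 10.2 ± 2.56 (log2 fold -1.63, limma adjusted p = 0.00146). Losses also covered the promoters of Arid5a, whose product stabilizes Il6 mRNA (21.7 ± 6.69 to 6.94 ± 3.23, log2 fold -1.55), of the mitochondrial elongation factor gene Tsfm (18.4 ± 4.78 to 5.56 ± 3.01, log2 fold -1.67) and of the olfactory receptor gene Olfr769 (18.2 ± 1.97 to 3.7 ± 0.777, log2 fold -2.04). Within the gene body of Tnfrsf1a, the main TNF receptor (chromosome 6, 125309401 to 125309900), capture rose from 16.4 ± 4.48 to 36.5 ± 9.6 (log2 fold 1.10, adjusted p = 0.0028). No region at Tnf or Tnfrsf1b was listed in any table.

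Of the 13125 regions listed at 3 weeks, 5693 were gained and 7432 lost, and 11153 passed the limma test (5291 gained, 5862 lost). They lay at or near 4391 named genes. In the authors' deposited table the median log2 fold change was 1.01 at gained regions and -0.26 at lost ones. The share gained was 48.7% among the 712 promoter regions against 43.1% of the others (Fisher's exact test, two-sided, adjusted p = 0.0034), 46.0% against 41.2% in gene bodies (adjusted p = 9.17e-08) and 40.4% against 46.3% in intergenic regions (adjusted p = 3.38e-11). At matched read level, the promoter share was set against 47.7% of other regions and no longer passed (adjusted p = 0.448), and the gene-body and intergenic shares stood against 43.6% and 42.8% (adjusted p = 0.0003 each). All 29 regions on the Y chromosome, near Uty, Ddx3y, Usp9y, Zfy1 and Zfy2 among others, were lost (adjusted p = 4.08e-07), while 23 of the 26 X promoter regions within 1 kb of a start were gained. These changes were not told apart from a different mix of male and female cells. At 4883 regions (37.2%) the deposited p was over 10 times smaller than Poisson counting of the recovered reads allows. These regions had small differences (median absolute log2 fold 0.21, against 0.91 elsewhere), and 11.5% of them were gained against 62.3% of the others. Without them 7565 regions passed (5031 gained, 2534 lost). Adjusting over all 902000 windows that the deposited q-values imply left 24 regions (6 gained, 18 lost), and a minimum absolute log2 fold of 1 left 3350, of which 3006 were gained and 344 lost.

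Gene groups at 3 weeks moved in both directions. TNF and NF-kB genes held 16 listed regions, of which 6 gained, 8 lost and 2 did not pass. Besides Tnfrsf1a, Nfkb2 rose (144 ± 3.85 to 186 ± 7.34, log2 fold 0.36) and the adaptor gene Traf5 fell (186 ± 14.9 to 148 ± 10.2, -0.33). Of 13 regions at cytokine, chemokine and receptor genes, 7 gained and 5 lost, with a gain at Lifr, the leukaemia inhibitory factor receptor (10.8 ± 3.93 to 31.7 ± 0.643, log2 fold 1.52). Interferon response genes held 5 regions (2 gained, 2 lost), among them a gain at the Oasl2 promoter (17.3 ± 5.17 to 35.1 ± 1.55, log2 fold 1.02). Of 37 extracellular matrix regions 18 gained and 13 lost, with Col5a3 up (60.8 ± 10 to 112 ± 9.61, log2 fold 0.88) and the laminin gene Lama1 down by a log2 fold of -0.28. Matrix proteases and inhibitors had 26 regions (12 gained, 9 lost), including losses at Adam33 (log2 fold -0.28) and Adamts10 (-0.31). Among 56 focal adhesion and cytoskeleton regions 26 gained and 23 lost, and 50 rather than 49 passed when adjusted over the list alone. Wnt genes held 26 regions (11 gained, 13 lost), with losses at the transcription factors Lef1 (log2 fold -0.32) and Tcf7l2 (-0.34). TGF-beta and BMP genes held 25 (10 gained, 12 lost). Capture fell at the receptor gene Tgfbr2 (132 ± 10.6 to 97.3 ± 7.76, log2 fold -0.44) and at Ltbp1 (-0.42) and rose at Bmp7 (0.22). Of 13 regions at limb patterning factors 6 gained and 6 lost, among them the Hoxa7 promoter (log2 fold -0.26). DNA methylation and chromatin regulators held 28 regions (14 gained, 11 lost). Capture rose at Dnmt1, the maintenance methyltransferase (63.0 ± 4.48 to 116 ± 6.78, log2 fold 0.87), and fell at the remodeller Smarca4 (-0.35).

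Cell cycle and apoptosis genes at 3 weeks held 14 regions (3 gained, 8 lost). Capture fell at Ccnd1, cyclin D1 (188 ± 2.72 to 148 ± 3.33, log2 fold -0.34). Of 16 regions at imprinted genes 14 were lost, 1 gained and 1 did not pass, among them Nespas (258 ± 14.7 to 208 ± 9.17, log2 fold -0.31), Rasgrf1 (-0.31) and Trappc9 (-0.25). Counted by gene, 1 of 13 imprinted genes was higher against 52.1% of other genes (Fisher's exact test, two-sided, adjusted p = 0.0533 over all lists and tables and 0.0267 within the table). Against genes of matched read level, no list passed on direction in any table. Of autosomal regions with a mean of 199.9 to 275.5 reads at this age, a range that holds the Nespas values, 12.6% were gained. All 11 regions at genes reported as differentially methylated in human rheumatoid synovial fibroblasts passed (5 gained, 6 lost), among them Tnfaip8 (571 ± 18.7 to 439 ± 8.75, log2 fold -0.38). Rheumatoid arthritis susceptibility loci held 28 regions (15 gained, 12 lost). Capture fell at Jazf1 (log2 fold -0.28) and, in a region chosen after its values were seen, at Tyk2, a kinase of cytokine receptors (202 ± 46.4 to 89.0 ± 20.2, -1.17). Synovial fibroblast markers had 9 regions (6 gained, 3 lost). Capture rose at the Wnt antagonist Sfrp1 (27.8 ± 3.74 to 57.9 ± 8.23, log2 fold 1.03) and fell at Ngfr (-0.44). Markers of other cell types were listed too. Macrophage and osteoclast genes held 7 regions (4 gained, 2 lost, Cx3cr1 at log2 fold -0.28) and lymphocyte genes 10 (6 gained, 2 lost, Bcl11b at -0.23). Endothelial and mural genes held 15 (4 gained, 5 lost, Emcn at -0.23, and 7 passing when adjusted over the list alone), skeletal muscle genes 18 (5 gained, 9 lost, Neb at -0.21) and cartilage, bone and fat genes 14 (8 gained, 3 lost, Sp7 at 0.20). Protocadherin and neuronal adhesion genes held 48 regions (19 gained, 21 lost), including losses at Csmd1 and Nrxn3 (log2 fold -0.29 each). Adjusted over the list alone, the other lists gave the counts above. Except at Tnfrsf1a, Lifr, Oasl2, Col5a3, Dnmt1, Tnfaip8, Tyk2, Sfrp1 and Cx3cr1, the list regions named for this age were of the kind whose deposited p was below the Poisson bound.

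At 8 weeks, when disease is established, the 6 largest promoter gains of the table included Rspo2, which encodes an enhancer of Wnt signalling (chromosome 15, 43001651 to 43002550). Capture there rose from 4.68 ± 2.78 in WT to 47.8 ± 43.3 in Tg197 (SD, n = 3 per group), a log2 fold change of 2.88 with a standard error of 0.75 (limma, adjusted p = 0.0428). Capture also rose at the promoter of the transcription factor gene Gata4 (2.93 ± 1.89 to 14.8 ± 3.75, log2 fold 2.08). It fell at the promoters of Gpr65, a proton-sensing receptor gene (chromosome 12, 99507051 to 99507800), from 15.8 ± 1.00 to 1.38 ± 2.4 (log2 fold -3.28), of the mitochondrial RNA polymerase gene Polrmt (12.9 ± 3.58 to 1.34 ± 1.33, log2 fold -2.73) and of the ubiquitin-like gene Ubl5 (14.5 ± 1.07 to 1.58 ± 1.39, log2 fold -2.79). At the promoter of Il1rl2, an IL-36 receptor gene, the values were 11.0 ± 7.38 in WT and 48.8 ± 52.6 in Tg197, which did not pass (adjusted p = 0.112).

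The table at 8 weeks listed 11975 regions near 3959 genes, 5811 gained and 6164 lost, and 6470 passed (2087 gained, 4383 lost). In the authors' deposited table the median log2 fold change was 0.77 at gained and -1.52 at lost regions. Gains made up 55.7% of 918 promoter regions against 47.9% of the others (adjusted p = 1.03e-05). The direction turned on autosomes, where promoter regions were gained less often (35.8% of 628 against 44.9%, adjusted p = 9.19e-06), and among regions that passed limma (23.2% against 32.8%, adjusted p = 7.65e-05). Gains made up 59.6% against 36.5% in intergenic regions (adjusted p = 1.59e-142) and 32.8% against 59.1% in gene bodies (adjusted p = 2.59e-177). Other regions of matched read level were gained at 52.7%, 44.6% and 48.6% for promoter, intergenic and gene-body regions (adjusted p = 0.0358, 0.0003 and 0.0003). On the X chromosome 926 of 981 regions were gained (94.4% against 44.4%, adjusted p = 1.1e-230, and against 72.1% of autosomal regions of matched level, adjusted p = 0.000704). The limma test was passed by 122 X regions, of which 80 were gained and 42 lost (65.6% against 31.6%, adjusted p = 5.94e-13). The gain on X differed between libraries: at X promoter regions within 1 kb of a start the median log2 ratio to the WT mean was 1.44, -0.27 and 1.12 in Tg197 libraries 1 to 3, and 255 of these 259 regions were listed as gained. Of the 259 regions 6 passed limma. Gains prevailed on chromosome 12 (512 of 754 regions, adjusted p = 2.14e-27), where 64 gained and 3 lost regions lay between 18 and 20 Mb, while chromosome 11 had 220 gained and 704 lost regions (23.8% against 50.6%) and chromosome 17 had 205 and 509 (28.7% against 49.8%). At matched level the last 2 stood against 39.2% and 41.7% (adjusted p = 0.000704 each), and among regions past limma chromosome 17 stood at 24.2% against 32.8% (adjusted p = 0.00152) and chromosome 12 at 68.3% against 29.1% (adjusted p = 1.47e-67). The count rested on single libraries. No region passed without Tg197 library 1 or 3 or WT library 1 or 2 (limma, with 6662, 5945, 4497 and 4382 regions at unadjusted p under 0.05), while 8849 passed without Tg197 library 2 (4458 gained, 4391 lost) and 5061 without WT library 3 (1234 gained, 3827 lost). A minimum absolute log2 fold of 1 left 1170 gained and 4448 lost. By limma, 0 passed with a pseudocount of 0.1 (7511 unadjusted) or adjusted over all 761000 windows (8127 unadjusted), and limma voom on the recovered reads passed 5872.

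Like the whole table, most gene groups at 8 weeks had more lost than gained regions among those that passed. Of 22 regions at TNF and NF-kB genes, 2 gained and 9 lost (13 adjusted over the list alone). Capture rose at the kinase gene Map3k7 (27.5 ± 5.1 to 59.5 ± 15.1, log2 fold 1.07) and fell at the Ltb promoter, lymphotoxin beta (68.0 ± 37.1 to 20.9 ± 4.52, -1.48). Ltb lay on chromosome 17 between 34 and 36 Mb, where 64 of 71 listed regions were lost, against a median of 7 regions per 2 Mb. Its loss was therefore not particular to this gene. Of 8 cytokine and receptor regions 7 were lost, among them Osmr, the oncostatin M receptor (25.3 ± 13.3 to 6.85 ± 3.88, log2 fold -1.78), and Csf1r (-1.17). Interferon response genes held 7 (1 gained, 3 lost). Capture fell at the Ifnar2 promoter (24.3 ± 4.96 to 8.1 ± 0.835, log2 fold -1.46) and Ifngr2 (-1.30). Extracellular matrix genes held 29 regions (3 gained, 14 lost), and proteases 19 (3 gained, 10 lost). Capture fell at Adamts14 (44.1 ± 20.8 to 8.86 ± 3.58, log2 fold -2.13) and Adamts8 (-2.91). Focal adhesion genes held 51 (9 gained, 14 lost, 16 passing when adjusted over the list alone). Capture fell at the parvin gene Parvb (log2 fold -1.71). Wnt genes held 24 (3 gained, 12 lost, 19 adjusted over the list alone), with the Rspo2 gain and a loss at the co-receptor gene Lrp5 (-1.65). TGF-beta and BMP genes held 16 (5 gained, 8 lost). Capture rose at Smad3 (4.41 ± 0.66 to 37.0 ± 28.6, log2 fold 2.44) and fell at the BMP mediators Smad1 (12.8 ± 2.89 to 1.38 ± 2.4, -2.98) and Smad9 (-1.99). Limb patterning genes held 36 (9 gained, 16 lost, 28 adjusted over the list alone). Capture rose at Hoxb3 (10.8 ± 1.37 to 66.0 ± 42.6, log2 fold 2.22). Of 19 chromatin regulator regions 12 were lost and 1 gained, with a loss at the histone methyltransferase gene Ehmt1 (-1.48).

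Cell cycle and apoptosis genes at 8 weeks held 14 regions, 7 lost and 7 not passing, with a loss at the pro-apoptotic gene Bax (16.4 ± 2.77 to 3.17 ± 2.86, log2 fold -2.43). Imprinted genes held 15 (3 gained, 5 lost, 7 adjusted over the list alone), with Trappc9 down (log2 fold -1.93). Genes reported in human rheumatoid fibroblasts held 7 (4 lost, 3 not passing, 5 adjusted over the list alone), including Wisp3 (29.1 ± 2.61 to 10.2 ± 4.38, log2 fold -1.49). Susceptibility loci held 41 (3 gained, 21 lost, 25 adjusted over the list alone). Capture fell at Hc, the complement C5 gene (19.1 ± 5.64 to 0.923 ± 1.6, log2 fold -3.65), and Aff3 (-2.49). Of 3 regions at synovial fibroblast markers the Pdpn promoter, podoplanin, was lost (21.9 ± 3.11 to 9.69 ± 1.96, log2 fold -1.11). Among markers of other cell types, macrophage genes held 3 regions (1 lost; 0 by limma adjusted over the list alone, with 2 at unadjusted p under 0.05 and 0 by voom). Lymphocyte genes held 12 (1 gained, 7 lost, Bcl11b at log2 fold -1.78) and endothelial genes 8 (1 gained, 6 lost, 8 adjusted over the list alone). Among the latter Vwf gained (13.6 ± 3.69 to 42.8 ± 26.7, log2 fold 1.45) and the Cldn5 promoter lost (-2.71). Cartilage, bone and fat genes held 7 (2 lost, 1 adjusted over the list alone, Col11a2 at -2.82). Col11a2 lay in the same stretch of chromosome 17 as Ltb, where most listed regions were lost. Skeletal muscle genes held 19 regions (3 gained, 4 lost) and protocadherin and neuronal adhesion genes 31 (5 gained, 5 lost). Adjusted over the list alone, these last lists gave 0 by limma, with 12 and 17 regions at unadjusted p under 0.05 and 7 and 10 by voom over the table. For the other lists the count adjusted over the list alone equalled that over the table, and the library dependence given above holds for every count at this age.

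**Figure D2:**
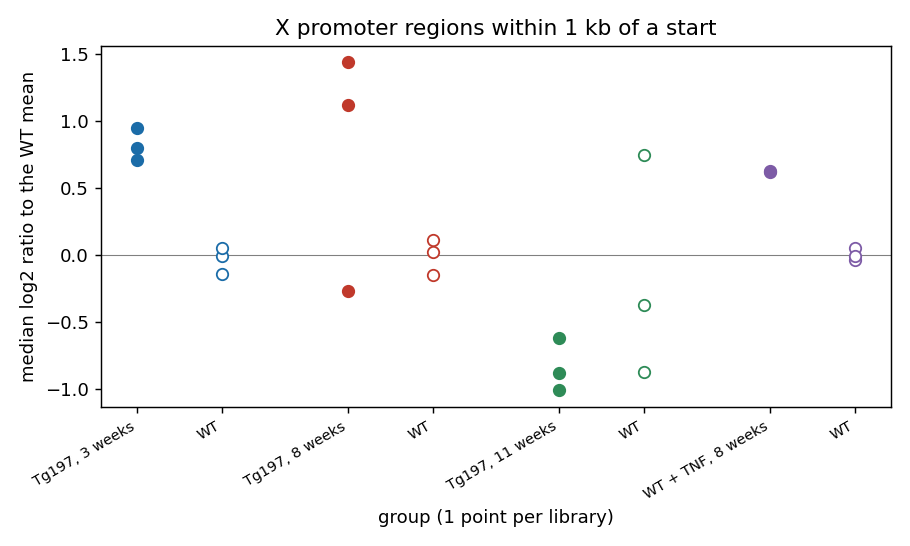
Each point is 1 library and shows its median log2 ratio to the WT mean over the X-chromosome promoter regions within 1 kb of a start in each table, with filled points for Tg197 or TNF-treated and open points for WT libraries. At 8 weeks Tg197 libraries 1 and 3 lay at 1.44 and 1.12 and library 2 at -0.27.

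At 11 weeks, the latest age, capture rose at the promoter of Esrrb, an orphan nuclear receptor gene (chromosome 12, 87701301 to 87702000), from 1.89 ± 1.86 in WT to 17.4 ± 2.88 in Tg197 (SD, n = 3 per group), a log2 fold change of 2.93 with a standard error of 0.67 (limma, adjusted p = 0.0219). Gains of this kind also covered the promoters of Pik3c2b, a class II phosphoinositide kinase gene (2.89 ± 3.51 to 17.1 ± 2.07, log2 fold 2.68), and of Mtrr, which keeps methionine synthase active (2.74 ± 2.72 to 15.0 ± 2.81, log2 fold 2.45). Losses covered the promoters of Dio2, the enzyme that activates thyroid hormone (chromosome 12, 91976601 to 91977100; 17.9 ± 2.45 to 4.44 ± 4.5, log2 fold -2.12), of the mitochondrial carrier homologue gene Mtch2 (63.9 ± 25.4 to 13.6 ± 8.25, -2.29) and of Afg3l1 (54.4 ± 13.4 to 7.55 ± 7.45, -3.39).

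The table at 11 weeks listed 7309 regions near 2666 genes, 3961 gained and 3348 lost, and 5694 passed (3633 gained, 2061 lost). In the authors' deposited table the median log2 fold change was 1.33 at gained and -0.80 at lost regions. Gene-body regions were gained more often than the others (58.7% against 50.5%, adjusted p = 6.72e-12) and intergenic ones less often (50.5% against 57.7%, adjusted p = 1.11e-09), and the 429 promoter regions did not differ (50.3% against 54.4%, adjusted p = 0.11). At matched read level, the promoter share stood against 55.8% and passed (adjusted p = 0.00747). On X 53 regions were gained and 146 lost (26.6% against 55.0%, adjusted p = 1.38e-14). Autosomal regions of matched level were gained at 39.3% (adjusted p = 0.000704), and among regions past limma X held 46 gained and 45 lost (50.5% against 64.0%, adjusted p = 0.0265). WT library 1 lay above the other libraries at X promoters within 1 kb of a start, at a median log2 ratio of 0.75. The densest stretches were chromosome 9 from 40 to 42 Mb (22 gained, 41 lost) and chromosome 8 from 18 to 20 Mb (2 gained, 45 lost), against a median of 5 regions per 2 Mb. Without Tg197 library 1 the count was 10 (limma, 5125 at unadjusted p under 0.05), and without Tg197 library 3 or WT library 2 it was 0 (4638 and 5186 unadjusted), while limma voom passed 5143. Adjusted over all 749000 windows it was 0 (5952 unadjusted), and a minimum absolute log2 fold of 1 left 3783 (2844 gained, 939 lost).

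Gains outnumbered losses at 11 weeks in most gene groups, as they did over the whole table, and no list differed in direction from the other genes of the table (Fisher's exact test, lowest adjusted p = 0.714, for focal adhesion genes). All 5 regions at TNF and NF-kB genes passed (2 gained, 3 lost). Capture fell at Tnfsf11, which encodes the osteoclast factor RANKL (16.6 ± 2.63 to 5.44 ± 2.03, log2 fold -1.48), and at Map3k14 (30.9 ± 3.2 to 13.5 ± 2.55, -1.14). All 4 cytokine and receptor regions passed (2 gained, 2 lost). Capture fell at the promoter of Lif (chromosome 11, 4167001 to 4167900; 48.5 ± 5.21 to 21.8 ± 3.21, log2 fold -1.13) and rose at Il6st, the shared receptor chain of the IL-6 family (7.47 ± 3.59 to 24.6 ± 3.58, 1.68). Interferon response genes held 1 region, at Ifngr2 (log2 fold -0.60), which did not pass over the table and passed adjusted over the list alone. Extracellular matrix genes held 24 regions (13 gained, 8 lost), with Col5a3 up (35.8 ± 1.95 to 81.0 ± 37.1, log2 fold 1.05) and Col14a1 down (18.3 ± 1.12 to 5.21 ± 0.78, -1.64). Proteases held 22 (11 gained, 6 lost). Capture rose at Ctsk, cathepsin K (17.1 ± 4.3 to 42.0 ± 12.2, log2 fold 1.24), and fell at Adamts14 (-0.96). Focal adhesion genes held 52 (32 gained, 11 lost, 44 adjusted over the list alone), with losses at Parvb (-0.89) and Vav3 (-1.12). Wnt genes held 19 (10 gained, 5 lost). Capture rose at the R-spondin receptor gene Lgr4 (0.65 ± 1.13 to 14.5 ± 6.94, log2 fold 3.34) and at Tcf7l2 (1.53) and fell at the Wnt1 promoter (132 ± 50.6 to 47.6 ± 10.8, -1.42). TGF-beta and BMP genes held 25 (12 gained, 5 lost), with Ltbp1 up (17.3 ± 12.6 to 63.4 ± 11.3, log2 fold 2.14) and Gdf6 down (-1.10). Limb patterning genes held 23 (9 gained, 9 lost). Capture rose at the Shox2 promoter (8.34 ± 3.86 to 31.0 ± 3.89, log2 fold 1.88) and fell at the promoters of Hoxd12 (51.7 ± 11.8 to 20 ± 7, -1.37) and Hoxd10 (-0.85).

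Chromatin regulators at 11 weeks held 10 regions (3 gained, 5 lost). Capture rose at Dnmt1 (52.4 ± 8.92 to 110 ± 28.9, log2 fold 1.03) and fell at Kdm2b (-0.83) and Hdac5 (-0.82). All 6 cell cycle and apoptosis regions passed (2 gained, 4 lost), with E2f3 up (log2 fold 1.36) and the p53-family gene Trp73 down (13.1 ± 2.84 to 3.31 ± 2.38, -1.83). Imprinted genes held 14 (5 gained, 4 lost, Trappc9 at log2 fold -0.86), genes reported in human rheumatoid fibroblasts 6 (2 gained, 2 lost, Map3k5 at 0.83). Susceptibility loci held 20 (12 gained, 5 lost, 18 adjusted over the list alone). Capture fell at Tyk2 (127 ± 6.14 to 55.4 ± 21.2, log2 fold -1.27) and Gata3 (-1.12). Synovial fibroblast markers held 5 (3 gained, 1 lost), with Sfrp1 up (11.2 ± 4.48 to 24.5 ± 1.64, log2 fold 1.13) and Smoc2 down (116 ± 11.7 to 55.5 ± 14.5, -1.07). Among other cell types, macrophage genes held 3 (1 gained, 2 lost, Mertk at log2 fold -0.58). Lymphocyte genes held 9 (4 gained, 3 lost, 8 adjusted over the list alone), with the Cd3e promoter down (18.5 ± 4.02 to 4.92 ± 2.37, log2 fold -1.79). Endothelial genes held 7 (5 gained, 2 not passing, Vwf at 1.75), muscle genes 7 (5 gained, 1 lost, Ttn at 1.04) and cartilage, bone and fat genes 9 (4 gained, 3 lost, Alpl at -2.15). Protocadherin and neuronal adhesion genes held 21 (14 gained, 3 lost). Capture rose at Csmd1 (4.91 ± 3.27 to 24.0 ± 10.9, log2 fold 2.16) and Pcdh15 (2.06). The remaining lists gave equal counts adjusted over the list alone.

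Exposure of WT cells to TNF at 8 weeks asked what the cytokine itself did. Capture rose at the promoter of Ido1, which encodes a tryptophan-degrading enzyme (chromosome 8, 25708701 to 25709300), from 1.65 ± 1.71 (n = 3) to 12.3 ± 1.9 (SD, n = 2), a log2 fold change of 2.57 with a standard error of 0.69 (limma, adjusted p = 0.0109). It rose as well at those of the small GTPase gene Rrad (2.16 ± 1.88 to 13.3 ± 0.495, log2 fold 2.45) and of Jmjd8 (1.08 ± 0.937 to 10.4 ± 0.728, 2.59). It fell at the promoters of Tbxas1, thromboxane synthase (chromosome 6, 38866951 to 38867800; 16.6 ± 3.44 to 0.995 ± 1.41, log2 fold -3.33), and of the fatty acid activating enzyme gene Acsl1 (21.7 ± 7.55 to 2.48 ± 3.51, -3.16). The promoters of Tlx2 and Tdrd12 were listed at 0 in both TNF-treated libraries, against 14.8 ± 2.29 and 14.9 ± 2.43 in WT. Within Tnfrsf1a (chromosome 6, 125312001 to 125312500) capture fell from 13.8 ± 1.42 to 4.09 ± 2.98 (log2 fold -1.67, adjusted p = 0.0126), at another position than the region gained in Tg197 at 3 weeks.

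The TNF table was the longest, with 16898 regions near 5628 genes, 5708 gained and 11190 lost, and 15855 passed (5028 gained, 10827 lost). The deposited values hold 1 TNF-treated library in positions 1 and 2. The authors' selection of regions and their fold changes may therefore count it more than once, which the retest does not undo. In the authors' deposited table the median log2 fold change was 0.67 at gained and -1.48 at lost regions. The share gained was 28.6% at 1009 promoter regions against 34.1% elsewhere (adjusted p = 0.000424), 23.9% against 43.2% in gene bodies (adjusted p = 2.66e-156) and 45.2% against 24.4% between genes (adjusted p = 3.19e-176). At matched read level, the promoter share stood against 29.1% and did not pass (adjusted p = 0.713), and the gene-body and intergenic shares stood against 36.1% and 32.0% (adjusted p = 0.0003 each). On autosomes 23.3% of promoter regions were gained against 32.6% (adjusted p = 3.43e-09). On X 480 regions were gained and 123 lost (79.6% against 32.1%, adjusted p = 8.26e-121), and on chromosome 11 there were 179 gained and 863 lost (17.2% against 34.9%, adjusted p = 1.53e-33). Autosomal regions of matched level were gained at 55.8% for X and 26.5% for chromosome 11 (adjusted p = 0.000704 each). Dense losses lay on chromosome 5 from 114 to 116 Mb (65 of 67 regions), chromosome 8 from 124 to 126 Mb (63 of 67) and chromosome 11 from 116 to 118 Mb (63 of 65), against a median of 10 regions per 2 Mb. Adjusted over all 817000 windows 0 regions passed (limma, 15904 at unadjusted p under 0.05, and 15754 by voom over the listed regions), and a minimum absolute log2 fold of 1 left 10538 (1200 gained, 9338 lost). Without TNF-treated library 1 (counted with its duplicate) or 3, gains numbered 2822 and 2928 and losses 8145 and 9038.

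Losses prevailed after TNF in most gene groups, as over the whole table. Of 22 regions at TNF and NF-kB genes 21 were lost and 1 did not pass. They included the NF-kB subunit genes Rela (15.7 ± 8.88 to 2.98 ± 2.8 (n = 2), log2 fold -2.15) and Relb (18.9 ± 8.19 to 3.36 ± 0.516, -2.10) and the kinase gene Ikbke (20.2 ± 10.4 to 3.48 ± 2.1, -2.22). All 11 cytokine and receptor regions were lost, among them Il6ra (22.8 ± 13.9 to 5.33 ± 4.73, log2 fold -1.99), Il34 (43.5 ± 15.2 to 12.1 ± 8.29, -1.87) and the Il1r1 promoter (-1.46). Interferon response genes held 10 (2 gained, 6 lost). Capture fell at Ifnar2 (log2 fold -1.73). Extracellular matrix genes held 53 (5 gained, 46 lost). Capture fell at Col4a1 (17.4 ± 3.05 to 2.85 ± 1.22, log2 fold -2.28) and the hyaluronan synthase gene Has1 (-1.27). Proteases held 39 (8 gained, 30 lost, Adamts3 at -1.66 and Adam12 at -1.56). Focal adhesion genes held 94 regions (16 gained, 72 lost, Itga6 at 0.44 and Itgb5 at -0.40), Wnt genes 49 (6 gained, 37 lost, Ror2 at -0.69), and TGF-beta and BMP genes 38 (8 gained, 29 lost, Ltbp4 at -2.34). All 32 limb patterning regions passed (12 gained, 20 lost), with Runx1 down (12.7 ± 0.844 to 0.50 ± 0.707, log2 fold -3.28). Of 32 regions at chromatin regulators 24 were lost and 5 gained, with losses at the methyltransferase gene Dnmt3a (20.1 ± 3.63 to 5.71 ± 2.45, log2 fold -1.69) and the demethylation gene Tet3 (54.4 ± 18.4 to 19.6 ± 3.21, -1.37). Of the list regions named for TNF, those at Itga6, Itgb5, Ror2 and Aff3 had a deposited p below the Poisson bound.

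Cell cycle and apoptosis genes held 20 regions in the TNF table (2 gained, 16 lost). Capture fell at Cdk1 (40.3 ± 4.14 to 14.0 ± 2.95, n = 2, log2 fold -1.47) and the Bax promoter (-1.28). All 18 imprinted gene regions passed (7 gained, 11 lost), with Trappc9 up (52.5 ± 5.07 to 89.9 ± 7.95, log2 fold 0.77) and Ddc down (-1.90). All 28 regions at genes reported in human rheumatoid fibroblasts passed (3 gained, 25 lost), among them the integrin gene Itga11 (33.0 ± 2.23 to 12.1 ± 1.26, log2 fold -1.38), and susceptibility loci held 48 (7 gained, 37 lost, Aff3 at 0.41). All 7 synovial fibroblast marker regions passed (2 gained, 5 lost). Capture fell at Sfrp1 (67.0 ± 7.38 to 35.3 ± 7.81, log2 fold -0.92) and the Smoc2 promoter (-1.22). Among other cell types, all 6 macrophage regions (2 gained, 4 lost, Aif1 promoter at log2 fold -1.85) and all 11 lymphocyte regions (4 gained, 7 lost, Pax5 at -1.18) passed. Endothelial and mural genes held 19 (8 gained, 10 lost, Cdh5 at -1.23), muscle genes 28 (10 gained, 16 lost, Tnni2 promoter at -3.21) and cartilage, bone and fat genes 14 (2 gained, 11 lost, Matn3 promoter at -1.18). In the protocadherin and neuronal adhesion genes 33 of 49 regions were gained and 15 lost. They included a gain at Odz4, now Tenm4 (26.9 ± 5.33 to 53.4 ± 15.9, log2 fold 0.95), and a loss at Dscam (-1.37). By gene, 12 of 20 were higher (60% against 20.4% of other genes, Fisher's exact test, two-sided, adjusted p = 0.0107 over 21 lists and 4 tables), which did not pass against genes of matched read level (adjusted p = 0.16). It was the single list of the 4 tables that passed on direction. No list had more or fewer listed genes than length-matched random lists. Every list gave the same count in this table adjusted over the list alone.

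The direction of change followed the read level of a region in every table. When autosomal regions were divided into 5 equal classes of read level, 92.0% were gained at 3 weeks, 10.2% at 8 weeks, 82.6% at 11 weeks and 17.6% after TNF in the lowest class. The highest class gave 5.3%, 79.9%, 6.3% and 82.9%. The slope of the log2 difference on log2 level, averaged over pairs of a treated and a WT library, was -0.30 at 3 weeks (range -0.37 to -0.24), 0.44 at 8 weeks (0.17 to 0.61), -0.41 at 11 weeks (-0.68 to -0.22) and 0.34 after TNF (0.21 to 0.45). Between libraries of the same group it stayed within 0.10, 0.22, 0.23 and 0.14 in either direction.

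**Figure D3:**
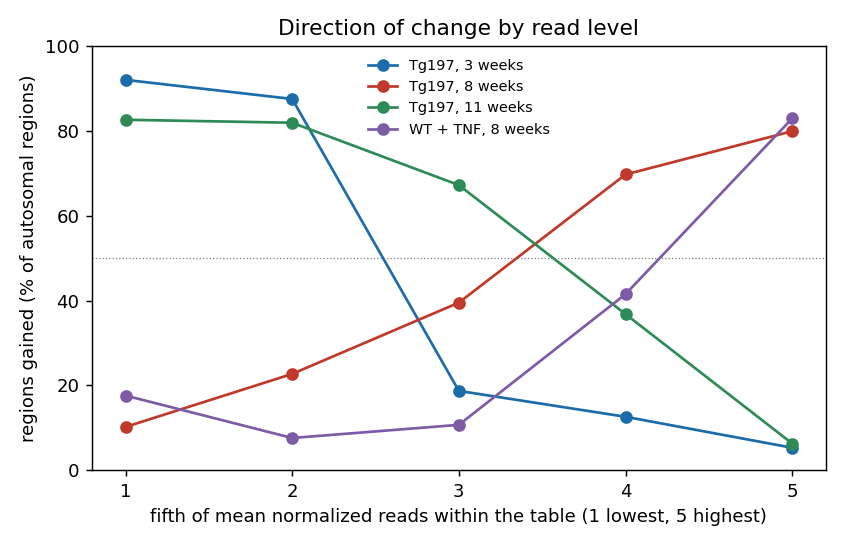
Lines give the percentage of autosomal regions gained (vertical axis) in each of 5 equal classes of read level, from lowest to highest (horizontal axis), in each of the 4 tables. The share fell from 92.0% to 5.3% at 3 weeks and from 82.6% to 6.3% at 11 weeks, and rose from 10.2% to 79.9% at 8 weeks and from 17.6% to 82.9% after TNF.

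Whether changes persisted with age was asked by overlapping the Tg197 tables, and the examples of shared regions in this and the next paragraphs were chosen after their values were seen. Between 3 and 11 weeks 308 regions overlapped, 6.58 times the 46.8 from random rotations (permutation adjusted p = 0.002, the smallest they can give), and 85.1% had the same direction (59.1% expected, Fisher's exact test, adjusted p = 1.69e-27, and 68.1% expected from read level, adjusted p = 0.0004). Of these, 175 passed in both tables: 58 gained in both, 95 lost in both and 22 opposite. Here and in the pairs below, rotated regions could fall on sequence that is not captured. An overlap above rotation was therefore likely for any 2 lists and does not by itself show that changes persisted. Shared gains outside chromosome 9 lay at Slc31a1, the copper transporter gene (5.9 ± 1.51 to 18.7 ± 2.68 at 3 weeks, log2 fold 1.52, and 4.91 ± 3.27 to 20.4 ± 10.7 at 11 weeks, log2 fold 1.91), and the Aox4 promoter (log2 fold 1.29 and 1.93).

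Of the 153 regions that passed with the same direction at 3 and 11 weeks, 69 (45.1%) lay in the first 25 Mb of chromosome 9, which makes up 1.01% of the autosomes. The stretch and its end were chosen after the shared regions were seen, so no test is given for it. Of 124 regions listed there at 11 weeks, 74 (59.7%) overlapped a 3-week region, against 3.26% elsewhere, and 72 of the 74 had the same direction. Inside it lay the Pdgfd promoter, Dnmt1 (20727651 to 20728600), Tyk2, Col5a3 and Smarca4 named above. Another region within Dnmt1 was lost at both ages (411 ± 11.8 to 346 ± 28.4, log2 fold -0.25, and 176 ± 17.1 to 120 ± 7.4, log2 fold -0.55). Shared losses there included Gucy1a2, a guanylate cyclase subunit gene (161 ± 42.4 to 47.3 ± 35.6 at 3 weeks, log2 fold -2.25, and 512 ± 51 to 167 ± 113 at 11 weeks, -1.93), and Casp12 (log2 fold -1.87 and -1.58). Shared gains included the Fat3 promoter (50.6 ± 10.8 to 102 ± 14.8, log2 fold 1.00, and 30.0 ± 7.38 to 63.0 ± 27, 1.00). The stretch held 44 regions at 8 weeks, of which 3 overlapped the 3-week table. The next counts leave out regions whose deposited p was below the Poisson bound. In the first 18 Mb, Tg197 library 3 at 3 weeks was the most changed library at 68 of 92 lost regions (73.9%, against 39.1% on other autosomal sequence). From 18 to 25 Mb it was so at 13 of 29 (44.8%). The library and the limit of 18 Mb were also chosen from these values.

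**Figure D4:**
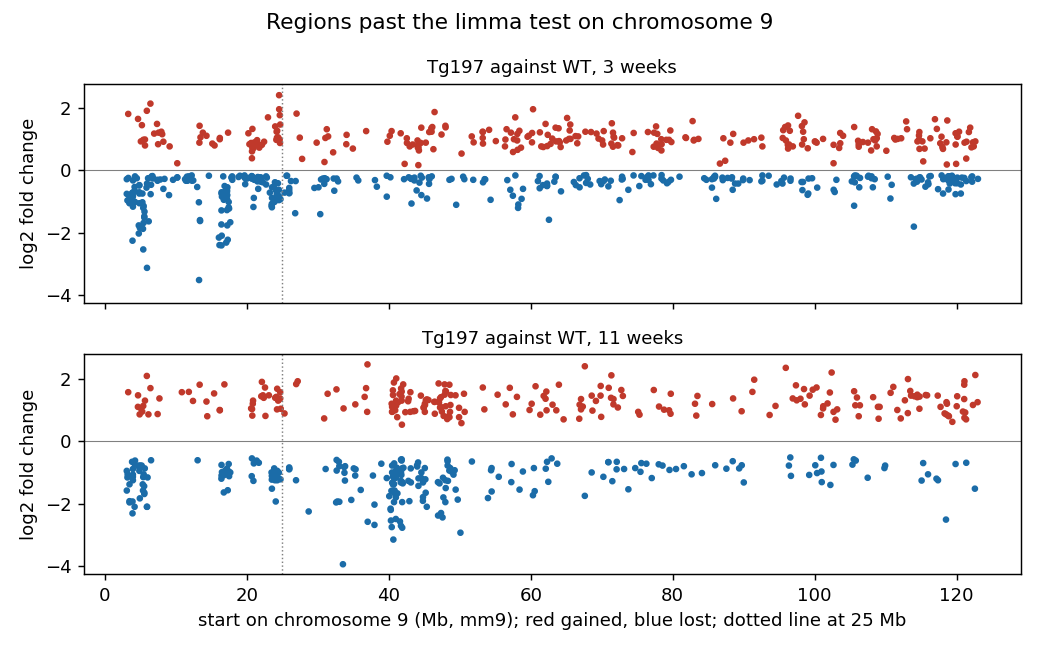
Points show the limma log2 fold change of regions that passed along chromosome 9 (start in Mb, mm9) at 3 and at 11 weeks, gained in red and lost in blue, with a dotted line at 25 Mb. Left of the line the tables listed 232 regions at 3 weeks (61 gained, 171 lost) and 124 at 11 weeks (45 gained, 79 lost).

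The 8-week table shared 586 regions with the 3-week table, 7.70 times the rotated mean, of which 34.6% had the same direction (47.2% expected, adjusted p = 6.83e-11). From the read level of the regions alone 32.0% was expected, and the call was lost (adjusted p = 0.184). It shared 327 with the 11-week table, 7.65 times, of which 41.0% had the same direction (47.7% expected, adjusted p = 0.0133). The latter call was lost with a 50% overlap (adjusted p = 0.0971), on autosomes (0.187), among regions past limma in both tables (0.56, with 53.3% against 50.2% expected), without chromosome 9 (0.0842) and against the 41.1% expected from read level (1.0). Among 192 regions that passed at both 3 and 8 weeks, 119 had opposite directions. Cdyl, a chromodomain gene, rose at 3 weeks (10.6 ± 6.63 to 35.4 ± 12.9, log2 fold 1.74) and fell at 8 weeks (14.2 ± 3.96 to 3.51 ± 0.881, -1.74), as did the Mtnr1a promoter (log2 fold 1.97, then 37.0 ± 5.88 to 17.7 ± 1.31, -1.02). The microRNA processing gene Rnasen, now Drosha, lost capture at both ages (log2 fold -2.46 and -1.72). A region of the same direction in all 3 Tg197 tables was found at 355 of 706 genes listed in all of them, against 379.9 with directions permuted (range 347 to 419, permutation p = 0.0519). The permutation p was 0.022 without regions under the Poisson bound (231 against 255.9) and 0.046 without chromosome 9 (337 against 359.7), but 0.615 at an authors' adjusted p under 0.01 (292 against 298.0) and 0.184 among regions past limma (165 against 178.0). Of the 10 taken by the fixed rule, Parvb, an adhesion gene, passed in all 3 tables. It was lost in 3 regions that do not overlap, at 3 weeks (84124601 to 84125100 on chromosome 15, 136 ± 3.01 to 95.5 ± 9, log2 fold -0.51), at 8 weeks (84135401 to 84136400, 32.5 ± 4.23 to 9.67 ± 3.99, -1.71) and at 11 weeks (84140401 to 84141350, 91.8 ± 10.8 to 49.1 ± 5.28, -0.89). The deposited p of the 3-week Parvb region was below the Poisson bound.

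Whether TNF exposure matched the change in Tg197 cells of the same age was asked by overlapping these tables, which share their WT libraries. Between the tables the deposited values of WT libraries 1 to 3 differed by 1 constant factor (coefficient of variation 0.0112%, 0.0101% and 0.00918% over 189, 188 and 153 regions of identical coordinates). They shared 1990 regions, 19.97 times the rotated mean of 99.7 (permutation adjusted p = 0.002, the smallest possible), and 94.8% had the same direction, against 68.2% expected from read level (adjusted p = 0.0004). By calculation from a bivariate normal distribution, unchanged groups with the same controls would share 0.8 of 761000 windows at the window threshold of 0.0001. They would share 1300 windows, with 99.9% in the same direction, if each listed region were counted as 1 window called. Independent lists of these lengths, counted so, would share 43.6 gained and 90.6 lost windows. These are counts of windows, so they cannot be set directly against the 1990 overlapping regions. The covariance of the log2 fold changes was 1.17 over the shared regions and 0.0871 in simulated unchanged groups. The shared regions were selected for large differences and the simulated values were not, so this contrast decides nothing. The WT libraries are too few to split, so part of the excess of shared regions may come from the shared controls. Of 1003 regions that passed in both tables, 257 were gained and 719 lost in both. Losses covered Hc (19.1 ± 5.64 to 0.923 ± 1.6 in Tg197 and 12.5 ± 1.15 to 0.995 ± 1.41 after TNF, log2 fold -3.65 and -2.96), the Ubl5 promoter (-2.79 and -2.61) and the tubulin gene Tubb6 at its promoter (-2.66 and -2.84). Gains covered Smad3 (log2 fold 2.44 in Tg197, and 3.52 ± 0.945 to 15.9 ± 5.58 after TNF, 1.89) and Prdm6, which encodes a zinc finger regulator (2.49 and 2.11). The TNF table and the Tg197 tables at 3 and 11 weeks shared 662 and 334 regions, of which 30.5% and 28.1% had the same direction (50.6% and 50.1% expected, adjusted p = 9.72e-27 and 5.93e-16). From read level 32.9% and 38.9% were expected, against which the pair with 3 weeks did not pass (adjusted p = 0.184) and the pair with 11 weeks did (adjusted p = 0.0004).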

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

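All tests of explanations in this part were chosen after the result was seen. The differences between ages stand out because every pair of libraries moved one way at one age and the other way at another, and these differences were not tested. The slope of the Tg197 difference on read level was 0.44 at 8 weeks against -0.30 at 3 weeks, and -0.41 at 11 weeks against 0.44 at 8 weeks. Of 586 regions shared by the 3-week and 8-week tables, 293 had non-overlapping groups in both, and 186 of these lay on opposite sides of WT, such as those at Cdyl and the Mtnr1a promoter. Between 8 and 11 weeks 69 of 143 such regions were opposite, and between 3 and 11 weeks 28 of 208. Over all regions shared by these pairs, 34.6%, 41.0% and 85.1% had the same direction, where read level alone gave 32.0%, 41.1% and 68.1% (adjusted p = 0.184, 1.0 and 0.0004), so opposite directions between 3 and 8 weeks were no more frequent than level gives. Chance alone separates 3 libraries from 3 at 10% of regions in a table, and listed regions were selected for a difference.

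The stretch of 25 Mb at the start of chromosome 9 held 69 of 153 regions that passed alike at 3 and 11 weeks, around Dnmt1, Tyk2, Gucy1a2 and Fat3. A change in copy number of the whole stretch is argued against, because 17 of these regions were gained beside 52 lost. A candidate explanation is a strain haplotype linked to the transgene or fixed in the colony, since CBA and C57BL/6J sequences may differ at CpG sites, and it would be carried at different doses if libraries pooled mice. At 8 weeks, however, the stretch held 44 regions (29 gained, 15 lost). Of these, 3 overlapped a 3-week region (6.8%, against 4.89% elsewhere). Regions not listed at 8 weeks have no value, so this cannot decide on a haplotype that sets Tg197 apart from WT at all 3 ages. Shares by library were taken without regions whose deposited p was below the Poisson bound. In the first 18 Mb, Tg197 library 3 at 3 weeks was the most changed at 73.9% of lost regions. It was highest at 59.3% of the 27 gained ones there, against 38.9% elsewhere, but library and limit were chosen from these values. From 18 to 25 Mb it was the most changed at 44.8% of lost and 35.5% of gained regions, which leaves different doses open. No genome sequence was used, so strain variants and a methylation change of the stretch cannot be told apart.

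Direction followed read level with slopes of opposite sign at 8 weeks and at the other ages. A scaling factor per library with no other difference would put every class of level on the same side of 50%, which is argued against by 10.2% gained in the lowest class at 8 weeks and 79.9% in the highest. Such a factor beside real changes may contribute, and nothing here decides it. Listed differences were smaller at high level (median absolute log2 fold 1.89 in the lowest class and 0.45 in the highest), but small differences can be listed at high level only. Differences in capture between single libraries, such as the share of densely methylated DNA recovered, may contribute. Slopes between libraries of a group reached 0.22 at 8 weeks, but regions were listed because the groups differ, so this comparison decides nothing, and an effect of age or disease stage remains untested.

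On the X chromosome 94.4% of regions were gained at 8 weeks. Against autosomal regions of matched read level the excess was smaller but remained. Read level is the mean of both groups and is itself raised by a gain. Matching on it therefore cannot say how much of the excess comes from level. Of all autosomal regions 44.4% were gained, and of those of the same level as the X regions 72.1%. A genotype effect present in every Tg197 library would need library 2 above the WT mean as well, and this library was above it at 36.2% of X regions, against 94.4% and 94.1% in the others, but 1 library excludes nothing. TNF-treated WT cells, which lack the transgene, were above the same WT libraries at 79.4% and 78.3% of the X regions of their table, so a property of these shared WT libraries may contribute and is not told from genotype or TNF here. A different mix of male and female cells between libraries may be involved, but over the 7 listed Y regions library 1 had a median of 58.3 normalized reads and the other libraries 13.8 to 23.5, so that X and Y do not move oppositely there, and 7 regions are too few to decide.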

How the results depend on the processing

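Limma voom, adjustment over all windows, removal of regions below the Poisson bound, regions past limma only, matching on level, lists not matched on length and removal of chromosome 9 were chosen after the data were seen. Of 102 checks of the counts behind each comparison, 78 stayed within 1.5 times the value reported and 24 did not, and the cause was not tested unless fewer regions or samples entered. Some of the 78 could hardly move. The minimum mean of 10 removed no region from the Tg197 tables, and overlap above rotation was likely for any 2 lists. A minimum absolute log2 fold of 1 lowered the regions passing to 3350 at 3 weeks, 3783 at 11 weeks and 10538 for TNF, but 5618 at 8 weeks was close to the value reported. Adjusting over all windows tested left 24 at 3 weeks and 0 elsewhere by limma (8127, 5952 and 15904 at unadjusted p under 0.05, and 5872, 5143 and 15754 by voom over the listed regions). With a pseudocount of 0.1 the 8-week count was 0 (7511 unadjusted). Leaving out each library in turn gave 10133 to 10848 at 3 weeks, 0 to 8849 at 8 weeks (0 without Tg197 library 1 or 3 or WT library 1 or 2, 8849 without Tg197 library 2, with 4458 gained and 4391 lost), 0 to 5511 at 11 weeks (10 without Tg197 library 1, 0 without Tg197 library 3 or WT library 2) and 10967 to 15870 for TNF, where 1 TNF-treated library was then assumed to vary like the WT ones. Gene lists passing on direction numbered 1, but 0 with promoter regions only, 2 with the region of smallest p, 2 among regions past limma and 0 at matched level, by Fisher's exact test. Lists passing on presence numbered 0, but 3 without length matching: protocadherin genes at 3 weeks (24 against 14.1 expected) and focal adhesion genes at 8 weeks (29 against 17.3) and 11 weeks (22 against 11.6). The 355 genes shared in direction by the Tg197 tables became 1 with promoters only, 165 among regions past limma and 231 without regions below the Poisson bound, since fewer regions entered. Feature classes (11 of 12 passing, 10 at matched level), chromosomes (40, range 38 to 43), and overlaps (6 of 6) stayed close in number. Within these counts the excess of gains at 8-week promoters over other regions, 7.8 percentage points, turned to -9.1 on autosomes and -9.6 among regions past limma, and that of chromosome 14 at 8 weeks from -14.2 to 1.9 among regions past limma. Agreement of direction passed in 6 of 6 pairs, in 5 under some settings, and in 3 against the share expected from read level. There the difference from the expected share went from -12.6 to 2.6 points between 3 and 8 weeks, and between 8 and 11 weeks it went from -6.7 to 3.1 among regions past limma. No named region that passed turned direction with a pseudocount of 0.1, with voom or with a library left out, but these regions were picked for their differences. All 39 at 8 weeks lost the call with this pseudocount and without Tg197 library 1 or 3 or WT library 1 or 2. All 53 at 11 weeks lost it without Tg197 library 1 or 3 or WT library 2. No paired analysis was possible because the values of a group are packed in 1 cell without replicate numbers. The planned second count-based test was not run, as the deposited values are normalized, and limma voom on the recovered reads was run in its place. Total depth is unknown, so which table it limits most cannot be said. In simulated data 1.5-fold changes were recovered at 13.4% at 8 weeks, 25.4% at 11 weeks, 32.8% for TNF and 73.1% at 3 weeks. These rates hold for the simulated spreads, which were 0 beyond counting at 3 weeks and for TNF, and may not hold for the real data.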

Other observations

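Tests of explanations reported here were chosen after the results were seen. Regions shared by the 3-week and 8-week Tg197 tables held a further group on chromosome 15, which was noticed in the data and not tested. Of 73 regions that passed alike at both ages, 22 (30.1%) lay on this chromosome, 21 of them lost, with starts from 12.8 to 87.4 Mb. They included the loss at Rnasen, from 25.7 ± 2.76 to 6.42 ± 5.61 normalized reads at 3 weeks and from 31.1 ± 10.7 to 9.01 ± 4.79 at 8 weeks (SD, n = 3 per group).

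On the Y chromosome at 3 weeks the Tg197 libraries had median log2 ratios to the WT mean of -0.85, -1.04 and -0.74, and the WT libraries 0.40, 0.0 and -0.57, while X promoter regions within 1 kb of a start stood at 0.80, 0.95 and 0.71 in the Tg197 libraries. The listed Y and X promoter regions thus moved oppositely at 3 weeks. A different mix of male and female cells was not tested at this age. After TNF, Y regions stood at 0.98 and 1.00 and these X promoters at 0.63 and 0.62 in the 2 distinct treated libraries.

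Other splits of the 6 libraries of a comparison were fitted in the same way. The real split passed 11153 regions at 3 weeks, 6470 at 8 weeks and 5694 at 11 weeks, and the highest of the other splits passed 59, 315 and 10. In each comparison 1 of 10 splits, the real one, gave as many regions, and 10 splits are too few for a share under 0.05. The regions were also listed because the real groups differ, which favoured the real split in advance. The contrast therefore cannot show a group difference.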
